A study of Arabidopsis thaliana with 8 samples.

How the data were processed

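RNA was sequenced from whole 7-day-old Arabidopsis seedlings of the wild type Col-0, the single mutants dek3-2 and dek4-2, and the double mutant dek3-2 dek4-2, called dd-2. Each of the 4 groups held 2 libraries, and the labels call them biological replicates. Each library has 1 deposited file with FPKM (fragments per kilobase of gene, scaled to library size) for 33557 genes, and this unit was taken per the file headers and the size of the values. The submitters' notes name HISAT2, featureCounts, edgeR and the build TAIR10 without versions, and they do not state which program wrote the FPKM or whether a scaling between libraries was added. The library kit was directional, but the notes do not say whether strand was used in counting, so values of overlapping genes on opposite strands are uncertain. Positions are TAIR10 coordinates as the files give them, counted from 1, and a locus that the files merge over several genes is given whole.

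The files hold no counts. In each library 99.9 to 100 percent of the low values on single-exon genes of 1000 to 6000 bp fell within 0.15 of a whole multiple of 1 fragment, where 30 percent would by chance. The step gave a relative depth of 0.799 (dd-2 replicate 2) to 1.12 (Col-0 replicate 2) of the mean library. A value of 1 FPKM on 1 kb of length, after an end correction of 180 or 190 bp, stood for 24.5 to 34.4 fragments. These steps give relative depth and counting error only, and no count test was run on them.

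The plan made before the data were examined covered the groups, the 7 comparisons, the gene lists, the rule for naming genes and most of the alternatives, and it assumed a table of counts. As the files held FPKM, the test was changed once the unit was known and before any test was run. The values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated statistics with a variance trend and robust estimation). One model held all 8 libraries with 1 mean per group. Genes with a mean of at least 1 FPKM over the 8 libraries were tested, 19017 in all, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Values are given as FPKM, mean ± SD with n = 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

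The comparisons were each mutant against Col-0, dd-2 against each single mutant, dek4-2 against dek3-2, and the interaction, which is the dd-2 minus dek3-2 difference less the dek4-2 minus Col-0 difference. In addition 27 gene lists with 359 genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with p adjusted over the 27 lists within a comparison. Members called were also counted when adjusted over the list alone. Genes were matched by locus code, and 32813 of the 33557 were found in the reference, while 744 were not. No list of transposable elements was formed, because the reference does not annotate that type.

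Genes named in the text follow a rule. For each mutant against Col-0 it took the 8 largest positive and 8 largest negative changes among called protein-coding genes with at least 2 FPKM in the higher group and both mutant libraries beyond both Col-0 libraries. The planned minimum was in CPM and was read as FPKM. For the other comparisons it took up to 5 called genes per direction by p. The 4 DEK genes, the 6 genes of the FLC clade, FT and SOC1 were always named, with up to 4 members of each other called list. Any other name is stated as chosen after its values were seen.

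The mutants share the 2 Col-0 libraries, which cannot be split, so overlap and correlation between them were set against 100 simulated draws of unchanged mutants sharing those libraries. Calls near the mutated genes were counted within 1 Mb, with Fisher's exact test, two-sided. The model was tested on simulated data built from these libraries with 200 of 19017 genes changed, over 20 draws. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2. Changes were added on that scale, so lower genes were not covered. In dd-2 against Col-0 it recovered 86.0 percent of 2-fold changes and 44.6 percent of 1.5-fold changes, with 7.9 false calls a draw. In the interaction it recovered 55.2 percent of 2-fold changes. Genes were drawn independently of each other, so variation shared between genes was not covered.

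The alternatives tried were median-of-ratios scaling, no filter on low values, a fit on the compared groups alone, the replicate number as a block, leaving out chloroplast and mitochondrial genes, a 2-fold minimum, leaving out each library in turn, and other windows around the mutated genes. Chosen after seeing the data were a pseudocount of 0.1, leaving out loci under 300 bp, removing each library's trends with transcript length, GC and purine share (splines of 5 degrees of freedom), and limma without variance trend or robust estimation.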

Results

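Gene expression was measured by RNA sequencing in whole Arabidopsis seedlings at 7 days, in 8 libraries of 4 genotypes with 2 libraries each. The genotypes were Col-0, dek3-2, dek4-2 and the double mutant dd-2, and the stated purpose was to find genes whose expression depends on DEK3 and DEK4, which encode DEK proteins, a family of chromatin proteins. The summed FPKM of a library ran from 839267 (dd-2 replicate 2) to 873796 (Col-0 replicate 1), and relative depth ran from 0.799 in dd-2 replicate 2 to 1.12 in Col-0 replicate 2. Between 18504 and 19283 genes reached 1 FPKM. Replicates correlated across genes with r from 0.982 in dek3-2 to 0.985 in dek4-2, and genes are not independent replicates. In dek4-2 replicate 1, 24.8 percent of genes were under 0.1 FPKM, against 16.1 to 18.8 percent in the other 7 libraries. The chloroplast genome took 1.19 to 1.43 percent of the FPKM in the libraries numbered 1 and 1.79 to 1.87 percent in those numbered 2.

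The mutated genes were examined first. DEK3 (chromosome 4, 13430527 to 13435770) stood at 59.2 ± 15.5 FPKM (SD, n = 2) in Col-0, 14.97 ± 2.39 in dek3-2, 64.0 ± 23.57 in dek4-2 and 18.7 ± 1.70 in dd-2. DEK4 (chromosome 5, 22538613 to 22543474) stood at 29.4 ± 8.15 in Col-0, 32.5 ± 7.74 in dek3-2, 14.3 ± 5.72 in dek4-2 and 15.9 ± 0.619 in dd-2. DEK3 fell by 1.90 on the log2 scale in dek3-2, where its adjusted p was 0.461 over all genes and 0.00165 adjusted over the list alone, the list being the 4 DEK genes. In dd-2 DEK3 fell by 1.59, with an adjusted p of 0.0828 over all genes and 0.00435 adjusted over the list alone. The DEK4 difference was -1.02 in dek4-2 (adjusted p = 1, and 0.0601 adjusted over the list alone) and -0.83 in dd-2 (adjusted p = 0.232, and 0.0687 adjusted over the list alone). The spread of these genes between replicates was wide, and with each library's length, GC and purine trends removed DEK3 passed over all genes in dek3-2 (adjusted p = 0.00205) and in dd-2 (adjusted p = 0.00211), as did DEK4 in dd-2 (log2 difference -1.04, adjusted p = 0.0483) but not in dek4-2 (adjusted p = 0.215). DEK1 was at 12.1 ± 3.01 FPKM in Col-0 and 15.2 ± 0.0592 in dd-2, and DEK2 at 8.99 ± 1.46 and 10.2 ± 0.183. Neither DEK1 nor DEK2 passed the test in any mutant against Col-0.

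**Figure D1:**
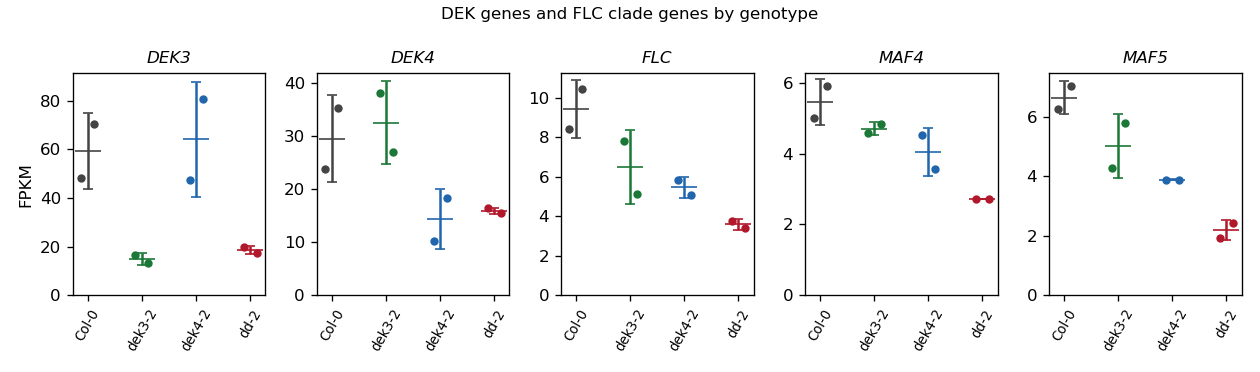
FPKM of DEK3, DEK4 and genes of the FLC clade by genotype. Points are single libraries, dashes are group means and bars are the SD of 2 libraries; FLC ran from 9.42 in Col-0 to 3.58 in dd-2.

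The comparison of dd-2 with Col-0 asked what differs where both genes are mutated. Of the 6 floral repressors of the FLC clade, MADS-box transcription factors that delay flowering, 3 were lower in dd-2, 1 of them by the test over all genes. MAF5 fell from 6.65 ± 0.557 to 2.18 ± 0.340 FPKM (SD, n = 2), a log2 change of -1.27 with an adjusted p of 0.0265. FLC, at 9.42 ± 1.45 in Col-0 and 3.58 ± 0.276 in dd-2 (log2 change -1.18), and MAF4, at 5.47 ± 0.647 and 2.73 ± 0.00136 (log2 change -0.79), passed when adjusted over the list alone (0.000544 and 0.000789) and not over all genes (0.0584 and 0.0642). FLC passed over all genes with median-of-ratios scaling (0.0367). Both FLC and MAF4 passed with the replicate number as a block, a fit given with the other processing alternatives below. In the remaining alternatives that kept every library neither passed, with adjusted p up to 0.106 for FLC. With 1 library left out the FLC log2 change ran from -1.32 to -1.04 and that of MAF4 from -0.89 to -0.69. MAF2, MAF3 and FLM, at 0.30, 0.15 and 0.04 on the log2 scale, did not pass, and FLM lay at -0.19 with library trends removed. As a list the clade was lower in camera (adjusted p = 0.0129), with 1 of 6 members called over all genes and 3 adjusted over the list alone, all 3 lower, and an adjusted p of 0.501 with an estimated correlation. Without Col-0 replicate 2 the list had an adjusted p of 0.0517. MAF5 lost its call without either Col-0 library (adjusted p = 0.0916 and 0.0961), either dek4-2 library (0.0596 and 0.0577) or either dd-2 library (0.200 and 0.0690). FT, a flowering signal, had a log2 difference of -0.44 (adjusted p = 0.163), and SOC1, a floral integrator, had 0.16 (adjusted p = 0.375).

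Over all tested genes 27 rose and 21 fell in dd-2, with MAF5 among the falls. The largest rises by the naming rule included BGLU30, a beta-glucosidase, from 2.29 ± 0.222 to 9.35 ± 1.42 FPKM, and the early nodulin-like gene ENODL1, from 4.08 ± 0.432 to 13.5 ± 3.77. HIS1-3, a linker histone gene induced by drought, rose from 49.0 ± 0.274 to 109 ± 18.1 FPKM (log2 change 1.12, adjusted p = 0.0206). The pectin methylesterase gene PME16 (log2 change 1.24), AT5G60630 (1.52), AT5G44440 (1.52) and AT5G39520 (1.13) also rose. The largest falls by the rule included MRD1, by 3.61 on the log2 scale (adjusted p = 3.27e-05), HEI10, an E3 ligase of meiotic crossovers (log2 change -1.10), AT5G11330, annotated as an oxidoreductase (-1.50), and AT2G43620, annotated as a chitinase (-1.35). AT3G28270 fell by 1.16 and AT5G05060 by 1.06. AT5G27889 and AT3G49460, named by the same rule, lie on loci under 300 bp where a value may rest on few fragments. AT5G27889 was listed at 0 in both Col-0 libraries and at 3.63 and 7.95 FPKM in dd-2, and AT3G49460 at 5.79 and 4.40 in Col-0 and at 0 in dd-2. The third call on such a locus, PSBL, named after its values were seen, had the largest fitted change of the 48 (adjusted p = 1.68e-05) and was listed at 47.6 and 72.7 in Col-0 and at 0 in dd-2.

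In all, 48 of 19017 genes were called in dd-2 against Col-0, 22 of them at 2-fold or more. An unadjusted limma p below 0.05 was found for 3529 genes, where 951 would be found by chance if p values were evenly spread. The counts in dek3-2 (655) and dek4-2 (374) lay below that number. It is therefore only a rough guide, and the excess in dd-2 was not tested. Without a filter on low values 26 were called, with only the libraries of both groups 16, and without variance trend or robust estimation 23. Many more were called with the replicate number as a block, a fit given with the other processing alternatives below. With median-of-ratios scaling 46 were called, 19 higher and 27 lower, and without chloroplast and mitochondrial genes 52 were called, 37 higher and 15 lower, so the balance of rises and falls depends on the scaling. The count fell to 10 without Col-0 replicate 1, to 15 without Col-0 replicate 2, to 16 without dek4-2 replicate 1, to 16 without dek4-2 replicate 2, to 15 without dd-2 replicate 1 and to 16 without dd-2 replicate 2. Of the 16 genes named by size of change, MRD1, AT3G49460, AT5G11330, AT5G60630 and AT5G39520 kept their calls whichever library was left out, and PME16 had the highest adjusted p on leaving out a library (0.230).

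**Figure D2:**
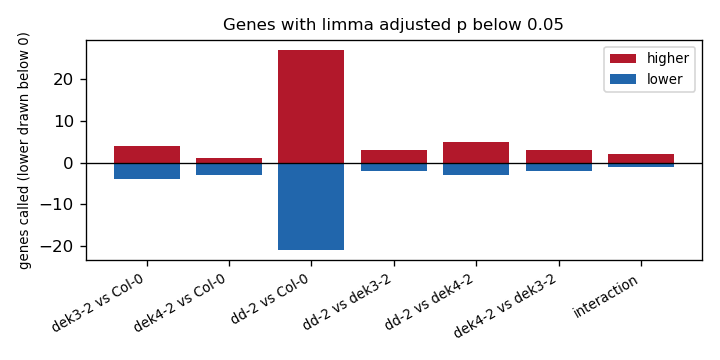
Number of genes called by limma at an adjusted p below 0.05 in each of the 7 comparisons, with higher genes above 0 and lower genes drawn under 0. The dd-2 against Col-0 comparison called 48 genes, and the other 6 called 3 to 8.

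Several gene lists were called by camera in dd-2 at the preset correlation, and none with an estimated correlation. Auxin response genes were higher as a list (camera adjusted p = 0.00138, and 0.501 with an estimated correlation), with all 15 tested members above 0 (14 under median-of-ratios scaling, and 15 of 16 without organelle genes). Of these, 7 rose adjusted over the list alone (3 under median-of-ratios scaling) and 0 over all genes, among them SAUR23 (log2 change 0.78), SAUR15 (0.77), GH3.5 (0.67) and SAUR20 (0.55). Genes of abscisic acid, salt and dehydration responses were higher too (adjusted p = 0.00138, and 0.925 with an estimated correlation), with 19 of 20 above 0. Here 5 rose adjusted over the list alone (3 under median-of-ratios scaling) and 0 over all genes: the dehydrins COR47 (0.62), ERD14 (0.62) and LTI30 (0.57), the abscisic acid synthesis gene NCED3 (0.84), and ABF3 (0.46). Without dd-2 replicate 1 this list had an adjusted p of 0.0627. Markers of the root endodermis were higher (adjusted p = 0.0216, and 0.925 with an estimated correlation), with 7 of 7 above 0 (6 under median-of-ratios scaling). PER64, at 3.17 ± 0.397 FPKM in Col-0 and 6.06 ± 0.222 in dd-2, and CASP1 were among the members that rose adjusted over the list alone, and 0 members were called over all genes. The endodermis list lost its call without Col-0 replicate 2 (adjusted p = 0.286) and without dd-2 replicate 1 (adjusted p = 0.0951).

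Nitrate assimilation genes were lower in dd-2 (camera adjusted p = 0.00906, and 0.501 with an estimated correlation), with 4 of 4 below 0. The nitrate reductase gene NIA1 (log2 change -0.51) and the nitrite reductase gene NIR1 (-0.30) fell adjusted over the list alone, and 0 members fell over all genes. Glucosinolate genes were lower as a list (adjusted p = 0.0295, and 0.854 with an estimated correlation), with 11 of 14 below 0 (10 without organelle genes). The glucosinolate gene MAM3, of side-chain elongation, was the 1 member that passed adjusted over the list alone, and it rose by 0.33, while under median-of-ratios scaling 4 members also fell. That list lost its call without Col-0 replicate 2 (adjusted p = 0.0796) and without dd-2 replicate 1 (adjusted p = 0.0627). The light-harvesting and Rubisco list did not pass camera (adjusted p = 0.179), but its members split. Adjusted over the list alone, 5 light-harvesting genes rose (4 under median-of-ratios scaling), among them LHCB2.2 by 0.80 and CAB3 by 0.52, and 6 genes fell, among them all 4 small-subunit genes of Rubisco, with RBCS3B at -0.46. These pigment-binding and carbon-fixation members had 0 calls over all genes. Of the flavonoid and anthocyanin genes 3 rose adjusted over the list alone, DFR (1.62), TT19 (0.93) and UF3GT (0.77), and the list did not pass camera (adjusted p = 0.551). LUX of the clock list and COR413-PM1 of the cold list rose adjusted over the list alone, at 0.32 and 0.35. These 2 genes, CAB3, ABF3, DFR, TT19 and UF3GT were named after their values were seen. The remaining 17 lists did not pass camera in dd-2 and had no member that passed adjusted over the list alone, apart from DEK3.

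The comparison of dek3-2 with Col-0 asked what differs where DEK3 alone is mutated. MRD1 (chromosome 1) fell from 15.1 ± 1.2 to 0.279 ± 0.0257 FPKM (SD, n = 2), a log2 change of -3.65 with an adjusted p of 1.99e-05. Its neighbour HEI10 fell from 2.58 ± 0.000403 to 0.596 ± 0.0619 FPKM (log2 change -1.17, adjusted p = 0.0342). The plant defensin gene PDF1.2C rose from 2.23 ± 0.518 to 10.7 ± 2.00 FPKM (adjusted p = 0.0150). AT5G60630 rose from 3.501 ± 0.246 to 10.04 ± 0.616 FPKM (adjusted p = 0.00898), and AT1G76960 rose from 28.2 ± 0.917 to 51.8 ± 5.36 FPKM (adjusted p = 0.0293). MRD1 and HEI10 overlap and are given with RHM2 as 1 merged locus, 19963047 to 19969757, so how fragments were split among them is not known. The other 3 calls lay on loci under 300 bp. PETG was listed at 55.9 and 51.4 FPKM in dek3-2 and at 0 in Col-0, PSBL at 47.6 and 72.7 in Col-0 and at 0 in dek3-2, and AT3G49460 at 0 in both dek3-2 libraries. In all 8 genes were called, 4 higher and 4 lower, and 655 had an unadjusted p below 0.05 where 951 would by chance. Without a filter on low values 14 were called, 8 higher and 6 lower, and without loci under 300 bp 5, 3 higher and 2 lower. Without dek3-2 replicate 2 the count was 16. MRD1 and AT3G49460 kept their calls whichever library was left out. HEI10 lost its call in each of the 8 cases (highest adjusted p = 0.215), AT1G76960 in 5 (0.176), and PDF1.2C (0.0753) and AT5G60630 (0.0852) in 2 each. The annotation used gives no gene type for PETG and PSBL, so the naming rule, which took protein-coding genes, did not pick them, and they were named after their values were seen.

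In dek3-2, camera called 10 lists, and with an estimated correlation each had an adjusted p of 0.652. Light-harvesting and Rubisco genes were lower (adjusted p = 4.71e-06), with 18 of 22 below 0 (19 under median-of-ratios scaling), among them LHCA1 (-0.23) and LHB1B1 (-0.69), and 0 were called over all genes or adjusted over the list alone. Jasmonate genes were higher (adjusted p = 0.0284), and CORI3 (log2 change 0.73), the defensin gene PDF1.2 (1.53) and the synthesis gene OPR3 (0.26) rose adjusted over the list alone, while 1 of these members passed under median-of-ratios scaling. Glucosinolate genes were higher (adjusted p = 0.00570), with MAM3 the 1 member that rose adjusted over the list alone, by 0.32, where 2 did under median-of-ratios scaling and 3 without organelle genes. Genes of abscisic acid responses (adjusted p = 0.00821), phosphate starvation (0.0284) and salicylate immunity (0.0486) were higher, and genes of iron deficiency (0.00703) and the FLC clade (0.0284) were lower, with 0 members called over all genes or adjusted over the list alone in any of these 5 lists. FLC was at -0.49 and MAF5 at -0.35. The DEK family list was lower (adjusted p = 0.0486, and 0.0516 under median-of-ratios scaling) with a mean of -0.43 and a median of 0.01, as DEK3 was the 1 member that fell. Seed maturation markers were higher (adjusted p = 1.85e-06), and this followed from dek3-2 replicate 1, without which the adjusted p was 0.0646. The seed storage protein gene CRA1 had a mean of 100 ± 135 FPKM in dek3-2 and 1.33 ± 0.535 in Col-0.

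Of these dek3-2 lists, light harvesting kept its call whichever library was left out. Without Col-0 replicate 1 the adjusted p was 0.0511 for abscisic acid responses, 0.890 for iron deficiency, 0.367 for jasmonate and 0.338 for phosphate starvation, whose direction turned. Without Col-0 replicate 2 it was 0.530 for the DEK family, 0.365 for the FLC clade and 0.349 for salicylate immunity. Without dek3-2 replicate 1 it was 0.188 for abscisic acid responses, 0.0760 for phosphate starvation and 0.304 for salicylate immunity. Without dek3-2 replicate 2 it was 0.498 for the DEK family, 0.256 for the FLC clade, 0.201 for glucosinolate, 0.0529 for iron deficiency, 0.467 for jasmonate and 0.146 for phosphate starvation. The DEK family also lost its call without dd-2 replicate 1 (0.0643) or dd-2 replicate 2 (0.0645). The other 17 lists did not pass, with the cold response list nearest (adjusted p = 0.0505).

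The comparison of dek4-2 with Col-0 asked what differs where DEK4 alone is mutated, with DEK4 transcript still at 14.3 FPKM and its difference from Col-0 not past the test. AT5G11330, annotated as an oxidoreductase (chromosome 5, 3617215 to 3618897), fell from 67.8 ± 1.203 to 20.8 ± 2.32 FPKM (SD, n = 2), a log2 change of -1.66 with an adjusted p of 0.00202, and it kept its call whichever library was left out. FLC, at 5.47 ± 0.520 FPKM (log2 change -0.68), and MAF5, at 3.88 ± 0.0104 (log2 change -0.65), were lower than in Col-0 when adjusted over the list alone (0.0168 each), with adjusted p = 1 over all genes. MAF4 was at -0.36 and did not pass. The other 3 calls lay on loci under 300 bp: AT5G27247 was listed at 4.80 and 11.3 FPKM in dek4-2 and at 0 in Col-0, and PSBL and AT3G49460 were listed at 0 in dek4-2. PSBL was named after its values were seen. MRD1 was at 31.5 ± 1.82 FPKM and HEI10 at 7.06 ± 0.452, and their log2 differences of 1.01 and 1.17 did not pass (adjusted p = 0.244 and 0.0542). In all 4 genes were called, 1 higher and 3 lower, or 2 higher and 3 lower with median-of-ratios scaling, and 374 had an unadjusted p below 0.05 where 951 would by chance. Without loci under 300 bp AT5G11330 was the 1 call. No other dek4 allele was sequenced. An effect of DEK4 on this gene can therefore not be told apart from a variant in the parental line of dek4-2. The count was 8 without Col-0 replicate 2, 9 without dek4-2 replicate 1 and 10 without dek4-2 replicate 2, and AT5G27247 lost its call in 6 of the 8 cases (highest adjusted p = 0.216).

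In dek4-2, camera called 6 lists. The FLC clade was lower (adjusted p = 3.23e-05, and 0.267 with an estimated correlation), with 6 of 6 below 0 (5 under median-of-ratios scaling). Abscisic acid response genes were higher (adjusted p = 4.30e-07, and 0.571 with an estimated correlation), with 19 of 20 above 0, and NCED3 was at 0.50. Nitrate assimilation genes were lower (adjusted p = 0.00191, and 0.267 with an estimated correlation), with 4 of 4 below 0, and NIA1 was at -0.33. Auxin response genes were higher (adjusted p = 0.0137, and 0.571 with an estimated correlation), with SAUR23 at 0.50, but the list had an adjusted p of 0.0811 without organelle genes. Iron deficiency genes (adjusted p = 0.0137, and 0.699 with an estimated correlation) and root hair markers (0.0157, and 0.644 with an estimated correlation) were lower. Apart from FLC and MAF5, these lists had 0 members called over all genes or adjusted over the list alone. The FLC clade and abscisic acid lists kept their calls whichever library was left out. Without Col-0 replicate 1 the adjusted p was 0.1002 for auxin, 0.907 for iron deficiency, whose direction turned, and 0.907 for root hair markers. Without dek4-2 replicate 1 auxin had 0.542. Without dek4-2 replicate 2 it was 0.959 for iron deficiency, whose direction turned, 0.382 for nitrate assimilation and 0.590 for root hair markers. The other 21 lists did not pass.

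The comparison of dd-2 with dek3-2 asked what the dek4-2 mutation adds to dek3-2. AT5G11330 fell from 69.4 ± 2.74 to 23.4 ± 3.53 FPKM (SD, n = 2; adjusted p = 0.00553). PIP1-5, an aquaporin gene, rose from 155 ± 0.119 to 255 ± 16.8 FPKM (log2 change 0.71, adjusted p = 0.0411), AT1G19530 rose by 1.28 (adjusted p = 0.0197) and AT3G62510 rose by 2.11 (adjusted p = 0.0443). PETG, on a locus under 300 bp, was listed at 0 in dd-2. In all 5 genes were called, 3 higher and 2 lower, and 2022 had an unadjusted p below 0.05. The fit with the replicate number as a block, given with the processing alternatives below, called many more. Without a filter on low values 10 were called, 5 higher and 5 lower, with only the libraries of both groups 3, all lower, with library trends removed 3, 1 higher and 2 lower, without organelle genes 3, 2 higher and 1 lower, and without variance trend or robust estimation 1, which was lower. The count was 8 without dek3-2 replicate 1, 11 without dek3-2 replicate 2 and 9 without dd-2 replicate 1. AT5G11330 and PETG kept their calls whichever library was left out, while PIP1-5 and AT3G62510 lost theirs in 6 of the 8 cases (highest adjusted p = 0.180 and 0.202) and AT1G19530 in 3 (0.104). Camera called 8 lists, none with an estimated correlation (lowest adjusted p = 0.336). Auxin response (adjusted p = 2.98e-06), endodermis, clock and abscisic acid genes were higher, and glucosinolate genes (adjusted p = 1.05e-05), seed maturation markers, nitrate assimilation genes and the FLC clade were lower. Seed maturation rested on dek3-2 replicate 1, without which the list changed direction (adjusted p = 0.783), and it also lost its call without dd-2 replicate 1 (0.352). Glucosinolate and auxin kept their calls whichever library was left out. Without dek3-2 replicate 1 the adjusted p was 0.0779 for the clock, 0.189 for the FLC clade and 0.171 for endodermis markers, and without dek3-2 replicate 2 it was 0.103 for abscisic acid and 0.0693 for nitrate assimilation. Without dd-2 replicate 1 it was 0.755 for abscisic acid, 0.235 for the clock and 0.0991 for endodermis markers, and without dd-2 replicate 2 it was 0.102 for the FLC clade and 0.154 for nitrate assimilation. Under median-of-ratios scaling the adjusted p was 0.0543 for the FLC clade and 0.0636 for nitrate assimilation. In the FLC clade MAF5 (-0.91), FLC (-0.69) and MAF4 (-0.62) fell adjusted over the list alone, as did FT (-0.63) among the floral promoters. By the same test 5 glucosinolate genes fell, among them CYP79F1 (-0.63) and CYP79B2 (-0.52), and 5 auxin genes rose (3 under median-of-ratios scaling), among them SAUR23 (1.07).

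The comparison of dd-2 with dek4-2 asked what the dek3-2 mutation adds to dek4-2. MRD1 fell by 4.62 (adjusted p = 8.70e-06) and HEI10 by 2.27 (adjusted p = 0.000730) on the log2 scale. PIP1-5 rose from 149 ± 0.827 to 255 ± 16.8 FPKM (SD, n = 2; adjusted p = 0.0252), AT5G60630 rose by 1.14, AT3G25930 by 1.25, AT5G39520 by 0.76 and AT5G26270 by 1.71, and AT5G27247 was listed at 0 in dd-2. In all 8 genes were called, 5 higher and 3 lower, or 4 higher and 6 lower with median-of-ratios scaling, and 3 higher and 3 lower without organelle genes. Without variance trend or robust estimation 5 were called, 3 higher and 2 lower. An unadjusted p below 0.05 was found for 2349. The count was 4 without dek3-2 replicate 1 and 4 without dek3-2 replicate 2. MRD1 and HEI10 kept their calls whichever library was left out, and the other 6 genes lost theirs in 5 or more of the 8 cases (highest adjusted p = 0.308, for AT5G26270). Endodermis markers (camera adjusted p = 0.00244) and auxin genes (0.0257) were higher, and light-harvesting genes and ferritins (0.0496 each) were lower, and under median-of-ratios scaling ferritins had an adjusted p of 0.0784 and light harvesting 0.1498. With an estimated correlation no list passed (lowest adjusted p = 0.655), and without dek4-2 replicate 2 the number of lists called was 0. DEK3 (-1.68), MAF5 (-0.62) and MAF4 (-0.43) fell adjusted over the list alone. By the same test 5 endodermis markers rose, among them PER64 (0.90) and CASP1 (0.75), and so did 2 of 3 root hair markers, EXPA7 (1.03) and EXPA18 (0.80), whose list did not pass camera (adjusted p = 0.0567). The root hair genes were named after their values were seen. Without dek4-2 replicate 2 the adjusted p of the endodermis list was 0.123 and that of auxin 0.272, and without dd-2 replicate 1 they were 0.0790 and 0.170. Ferritins lost their call without dek3-2 replicate 1 (0.0629), dek3-2 replicate 2 (0.0628), dek4-2 replicate 2 (0.267) and dd-2 replicate 1 (0.368). Light harvesting lost its call without either dek3-2 library (0.0872 and 0.0867), either dek4-2 library (0.138 and 0.123) or either dd-2 library (0.219 and 0.0608).

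Set against each other, the single mutants differed in few genes. MRD1 was higher in dek4-2 than in dek3-2 by 4.66 (adjusted p = 4.06e-06) and HEI10 by 2.33 (adjusted p = 0.000388), and AT5G11330 was lower by a log2 difference of -1.69 (adjusted p = 0.00129). AT5G27247 and PETG, on loci under 300 bp, made up the 5 genes called, 3 higher and 2 lower, or 3 higher and 1 lower without organelle genes. Without loci under 300 bp 3 were called. An unadjusted p below 0.05 was found for 520. AT5G27247 lost its call in 6 of the 8 cases with a library left out (highest adjusted p = 0.141), and the other 4 kept theirs. The count was 10 without dek3-2 replicate 1, 13 without dek3-2 replicate 2, 13 without dek4-2 replicate 1 and 13 without dek4-2 replicate 2. Light-harvesting genes (camera adjusted p = 6.71e-09) and auxin genes (0.000186) were higher in dek4-2, and seed maturation markers (1.90e-07), glucosinolate genes (5.94e-06) and root hair markers (0.00476) were lower. No list passed with an estimated correlation (lowest adjusted p = 0.403). The seed maturation difference rested on dek3-2 replicate 1, without which the adjusted p was 0.121. Auxin lost its call without dek3-2 replicate 2 (0.304) and dek4-2 replicate 1 (0.0836), and root hair markers without dek3-2 replicate 2 (0.143) and dek4-2 replicate 2 (0.259). Light harvesting and glucosinolate kept their calls.

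**Figure D3:**
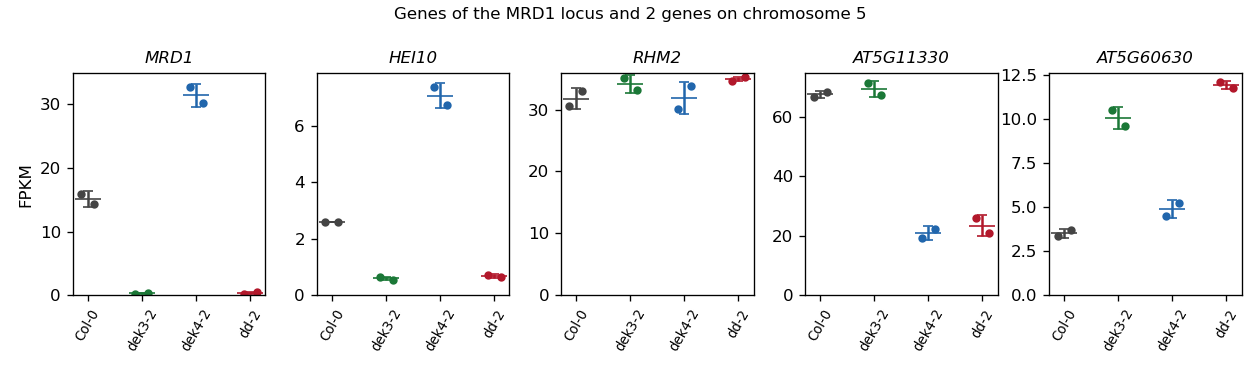
FPKM of MRD1, HEI10 and RHM2, which share a merged locus on chromosome 1, and of AT5G11330 and AT5G60630 on chromosome 5, by genotype, each panel with its own axis from 0. Points are single libraries, dashes are group means and bars are the SD of 2 libraries; MRD1 was at 0.279 in dek3-2, 0.322 in dd-2, 15.1 in Col-0 and 31.5 in dek4-2.

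The interaction asked whether dd-2 departs from the sum of both single mutants on the log2 scale. The 3 genes called were PETG, PSBL and AT3G49460, all on loci under 300 bp with values listed at 0 in 6 of 8 libraries. With such loci left out limma called 0 genes, and 693 of all tested genes had an unadjusted p below 0.05 where 951 would by chance. Without a filter on low values 8 were called, 6 higher and 2 lower. The count was 6 without Col-0 replicate 1, 7 without Col-0 replicate 2, 7 without dek3-2 replicate 1, 11 without dek3-2 replicate 2, 9 without dek4-2 replicate 1, 11 without dek4-2 replicate 2, 10 without dd-2 replicate 1 and 6 without dd-2 replicate 2. AT3G49460 lost its call without dek3-2 replicate 1 (adjusted p = 0.0644) and without dd-2 replicate 2 (0.0552), and PETG and PSBL kept theirs. The 3 calls were 2 higher and 1 lower, or 2 higher and 2 lower with median-of-ratios scaling and 1 higher and 0 lower without organelle genes. For FLC the interaction was -0.00 (SE 0.26, adjusted p = 1.00), for MAF4 -0.25 (SE 0.20) and for MAF5 -0.27 (SE 0.22), none of which passed. Camera called 7 lists, among them auxin response and endodermis markers above the sum and glucosinolate genes below it, and no list passed with an estimated correlation (lowest adjusted p = 0.656).

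The overlap of calls was measured against shared controls. dek3-2 and dd-2 shared 5 calls in the same direction (expected 0.00568 higher and 0.00442 lower by chance, and 0.02 a draw in simulated unchanged mutants), which included MRD1, HEI10 and AT5G60630. dek4-2 and dd-2 shared 3 calls (expected 0.00142 and 0.00331, simulated 0.01), which included AT5G11330. dek3-2 and dek4-2 shared 2, PSBL and AT3G49460 (expected 0.000210 and 0.000631, simulated 0.02). Unchanged mutants gave almost no calls (0.15 a draw for dek3-2 in the simulation with 200 changed genes in dd-2). Neither these simulated counts nor the chance values can therefore show how much overlap shared controls give between lists of this length. PSBL and AT3G49460, above 0 only in the Col-0 libraries, were shared calls in every pair. Without loci under 300 bp the shared calls were 3, 1 and 0. With 1 library left out the counts ran from 4 to 9, 3 to 8 and 2 to 6, with the highest of each without Col-0 replicate 2. Across genes, the log2 changes of dek3-2 and dd-2 correlated with r = 0.545 where the shared Col-0 libraries alone gave 0.502 in simulation, those of dek4-2 and dd-2 with 0.492 against 0.504, and those of dek3-2 and dek4-2 with 0.450 against 0.504. The covariances were 0.0376, 0.0306 and 0.0238 against simulated values of 0.0170, 0.0174 and 0.0171. Genes are not independent replicates. Shared controls alone give correlations of about this size. All 3 covariances were above the simulated means, most for dek3-2 and dd-2. More spread in the Col-0 libraries than was drawn would also raise them, and the draws took genes as independent. A covariance above the simulated mean therefore does not by itself show a shared effect.

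Calls near the mutated genes were counted to look for a linked segment. No called gene lay within 1 Mb of DEK3 in dek3-2 (0 of 8 calls, with 433 tested genes in the window) or of DEK4 in dek4-2 (0 of 4, with 386). In dd-2 0 of 48 calls lay near DEK3 (Fisher's exact p = 0.629), and 1, ENODL1, lay near DEK4 (odds ratio 1.03, Fisher's exact p = 0.627). With library trends removed the only call within 1 Mb of DEK3, in dek3-2 and in dd-2, was DEK3 itself, and the only dd-2 call near DEK4 was DEK4 itself. These counts were too small to exclude a several-fold excess, since the upper 95 percent bounds of the odds ratio were 25.2 for DEK3 in dek3-2 and 73.3 for DEK4 in dek4-2.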

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

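The search for calls near DEK3 and DEK4 was planned, and the tests on PETG, PSBL, AT3G49460, MRD1, RHM2 and the replicate spread of DEK3 and DEK4 were chosen only after the result was seen.

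In the test of whether dd-2 departs from the sum of the single mutants, 3 genes and 7 lists passed. The interaction was 2.60 for AT3G49460, 5.90 for PSBL and -5.77 for PETG on the log2 scale. PETG and PSBL are chloroplast genes on loci of 114 and 117 bp, and AT3G49460 spans 266 bp. Each PETG value above 0 was set against the lowest value of genes of the same span, its own included, with at least 2 other genes. It came to 1 fragment, which says only that no other such gene was lower in that library. Values of 1 or 2 fragments on short genes are a candidate explanation for that call, and this reading cannot decide it. The largest value came to 2.03 fragments for PSBL, with 0 other genes of that span to read it against in its library, and to 2.68 for AT3G49460, with 1. For these 2 genes few fragments and a real loss in the mutants cannot be told apart, because too few genes share their span. Both genes were at 0 in every library of the 3 mutants, so dd-2 could not fall below the single mutants. PSBL changed by -5.90 and AT3G49460 by -2.60 in each single mutant, the interaction with its sign turned. Their departure from the sum thus follows from the floor at 0 under either reading. With loci under 300 bp left out limma called 0 genes in the interaction, and before that 693 had an unadjusted p below 0.05.

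The 7 lists that passed in the interaction were auxin response (adjusted p = 0.000615), endodermis markers (0.000713) and the clock (0.0295), above the sum, and glucosinolate (0.000615), seed maturation (0.00491), ferritins (0.0295) and jasmonate (0.0295), below it. With an estimated correlation all 7 failed (adjusted p from 0.656 to 0.786). Under median-of-ratios scaling seed maturation (0.127), ferritins (0.0543), jasmonate (0.0904) and the clock (0.0811) lost their calls. Jasmonate had 8 of 17 members above 0 with a median of -0.02, and 4 of 17 with a median of -0.08 under that scaling. Glucosinolate kept its call whichever library was left out. Auxin lost its call without dek4-2 replicate 2 (adjusted p = 0.0653), and endodermis markers without Col-0 replicate 1 (0.0879) and dek4-2 replicate 2 (0.0653). Seed maturation lost its call and changed direction without dek3-2 replicate 1 (0.784), and lost it without dek4-2 replicate 1 (0.108) and dd-2 replicate 1 (0.304). The clock lost its call without dek3-2 replicate 1 (0.0565), dek3-2 replicate 2 (0.0833), dek4-2 replicate 1 (0.0714), dek4-2 replicate 2 (0.0653) and dd-2 replicate 1 (0.304). Ferritins lost it without Col-0 replicate 1 (0.241), dek3-2 replicate 2 (0.171), dek4-2 replicate 2 (0.196) and dd-2 replicate 1 (0.357), and jasmonate without Col-0 replicate 1 (0.292), dek3-2 replicate 2 (0.207), dek4-2 replicate 2 (0.477) and dd-2 replicate 2 (0.504). PER64 (0.96), CORI3 (-0.82), CYP79F1 (-0.67), CYP79B2 (-0.47) and CYP83A1 (-0.41) passed adjusted over the list alone.

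MRD1 and HEI10 fell in both lines with the dek3-2 allele, and in dek4-2 their log2 differences of 1.01 and 1.17 were above 0 without passing. Fragments moved between these genes and RHM2 would have changed RHM2 by 0.35 in dek3-2, -0.66 in dek4-2 and 0.35 in dd-2. The 95 percent intervals of RHM2 left those values out in all 3, with a log2 difference of 0.00483 in dek4-2. That test cannot decide for MRD1 or HEI10, whose fragments were pooled in the values computed. In the reference MRD1 ends at 19964712 and HEI10 at 19966952, while RHM2 starts at 19966944. MRD1 fragments, and nearly all HEI10 fragments, could thus not be expected in RHM2 whatever the cause. HEI10, from 19963267 to 19966952, overlaps MRD1 in the merged locus, and how fragments were split between HEI10 and MRD1 was not tested. A variant at that locus in the parental line of dek3-2 stays open, as 2 of the 5 dek3-2 calls on loci of at least 300 bp lie there and no other dek3 allele was sequenced. An effect of DEK3 on the locus is the biological alternative, and it cannot be told apart from such a variant. The planned search for linked segments left the same question open at the mutated genes, with upper bounds of the odds ratio of 25.2 at DEK3 and 73.3 at DEK4.

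DEK3 and DEK4 differed between replicates by 0.46 on the log2 scale on average, against 0.18 for all tested genes. With each library's trends with transcript length, GC and purine share removed, this fell to 0.428 of its size, while for all tested genes the ratio was 0.955. Purines make up 64.2 percent of DEK3 and 65.7 percent of DEK4, where the median of tested genes was 50.5 percent. Such library trends are therefore a candidate explanation for the spread. With them removed DEK3 passed over all genes in dek3-2 and dd-2 and DEK4 in dd-2, but DEK4 in dek4-2 did not (adjusted p = 0.215). No biological explanation for the spread was tested.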

How the results depend on the processing

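The pseudocount of 0.1, the removal of loci under 300 bp, the removal of library trends and the variance model without trend or robust estimation were chosen after seeing the data, and the other alternatives were planned. DESeq2 and the legacy quasi-likelihood method were not run, since the deposited values are not counts. No called gene that the text names reversed its direction, but 4 called lists changed direction on leaving out a library and were then no longer called: iron deficiency in dek4-2 without Col-0 replicate 1 (adjusted p = 0.907) or dek4-2 replicate 2 (0.959), phosphate starvation in dek3-2 without Col-0 replicate 1 (0.338), and seed maturation without dek3-2 replicate 1 in dd-2 against dek3-2 (0.783) and in the interaction (0.784). Among genes that were not called, FLM in dd-2 went from 0.04 to -0.19 with library trends removed. The cause was not tested except where the setting itself removes genes or libraries.

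With median-of-ratios scaling 9 lists passed in dek4-2 against dek3-2 and 4 in the interaction, and 36 of the 48 dd-2 calls were kept. Without a filter on low values the calls were 14 in dek3-2, 26 in dd-2, 10 in dd-2 against dek3-2 and 8 in the interaction, the overlaps were 4 for dek3-2 with dek4-2 and 5 for dek4-2 with dd-2, and 0 calls of dd-2 lay near DEK4. With only the libraries of the groups compared, which leaves fewer samples, the calls were 16 in dd-2 and 3 in dd-2 against dek3-2, with 0 near DEK4. With chloroplast and mitochondrial genes left out there were 3 calls in dd-2 against dek3-2 and 1 in the interaction, 1 shared by dek3-2 and dek4-2, and 1 of dd-2 near DEK3. At 2-fold or more dd-2 had 22 calls.

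With the replicate number as a block the calls were 305 in dd-2, 74 in dd-2 against dek3-2, 13 in dd-2 against dek4-2 and 5 in the interaction, with 11 lists in the interaction and 3 and 7 dd-2 calls near DEK3 and DEK4. All 48 dd-2 calls were kept there, and FLC (adjusted p = 0.0351) and MAF4 (0.0472) passed over all genes. The numbers were not taken to pair the libraries. The differences between replicate 1 and replicate 2 correlated between genotypes at -0.0651 to 0.230, not over 0.1 in every pair of groups. The chloroplast share did part the numbers in all 4 genotypes, and a batch that follows the number stays open.

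With camera's estimated correlation 0 lists passed in each of the 7 comparisons. A window of 0.5 Mb held 0 dd-2 calls at DEK4, and a window of 3 Mb held 3 at DEK3 and 4 at DEK4. With loci under 300 bp left out, which removes tested genes, the calls were 5 in dek3-2, 1 in dek4-2, 3 in dek4-2 against dek3-2 and 0 in the interaction, and the overlaps were 0 for dek3-2 with dek4-2, 3 for dek3-2 with dd-2 and 1 for dek4-2 with dd-2. With library trends removed there were 3 calls in dd-2 against dek3-2, 1 list in dd-2 against dek4-2, and 1 call near DEK3 in dek3-2 and 1 in dd-2, which was DEK3 itself in both. Without variance trend or robust estimation the calls were 23 in dd-2, 1 in dd-2 against dek3-2 and 5 in dd-2 against dek4-2, with 0 near DEK4. Of the 46 calls of named genes, 18 were lost with only the groups compared, which could test 43 of them, 18 without variance trend or robust estimation, 10 without a filter, 9 with library trends removed, 4 at 2-fold, 3 of the 42 tested with organelle genes left out, 2 each with median-of-ratios scaling and a pseudocount of 0.1, 1 with the block and 0 of the 34 tested with short loci left out. MAF5 in dd-2 lost its call without a filter (adjusted p = 0.0523) and with only the groups compared (0.0698), in a range from 0.0116 to 0.0698 over the alternatives that keep every library.

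Leaving out 1 library leaves a group of 1, which is assumed to vary like the others. The calls then ran from 7 to 16 in dek3-2, 3 to 10 in dek4-2, 10 to 35 in dd-2, 5 to 11 in dd-2 against dek3-2, 4 to 10 in dd-2 against dek4-2, 5 to 13 in dek4-2 against dek3-2 and 6 to 11 in the interaction. Lists ran, in the same order, from 6 to 11, 4 to 13, 3 to 10, 4 to 8, 0 to 5, 5 to 8 and 2 to 14. Overlaps ran from 2 to 6 for dek3-2 with dek4-2, 4 to 9 for dek3-2 with dd-2 and 3 to 8 for dek4-2 with dd-2. Calls near the mutated genes ran from 0 to 1 for DEK3 in dek3-2, 0 to 0 for DEK4 in dek4-2, and 0 to 1 for both genes in dd-2. MRD1, AT3G49460 and AT5G11330 kept their calls against Col-0 in the mutants where they were called.

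What the design can see was tested on simulated data with 2 libraries in each group, and the part that depth plays in it was not tested. Among simulated changes in dd-2, 44.6 percent of 1.5-fold and 86.0 percent of 2-fold changes were recovered, and 9.03 and 55.2 percent for the interaction. The changed genes all had a mean log2(FPKM + 1) above 2, so lower genes were not covered. Each draw held 200 changed genes, with every gene drawn independently from the fitted spread. With fewer changed genes the adjusted threshold is stricter, so these shares may be too high for comparisons with few calls.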

Other observations

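The comparison of the single-mutant change with the change on the other mutant's background, the count of intermediate genes and the jacalin-related family were all chosen after the result was seen.

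Jacalin-related lectins, of which some act in glucosinolate breakdown, included 4 genes that rose in dd-2. JAL22 went from 37.3 ± 2.39 FPKM in Col-0 to 74.1 ± 14.3 in dd-2 (SD, n = 2), NSP1 from 97.0 ± 6.29 to 157 ± 14.9, PBP2 from 14.3 ± 0.618 to 25.5 ± 1.72 and JAL35 from 80.1 ± 4.49 to 132 ± 11.2. The limma adjusted p was 0.0178 for PBP2 and 0.0483 for JAL22, NSP1 and JAL35, near the threshold. NSP1, PBP2 and JAL35 lie close together on chromosome 3 (5566086 to 5599224), so they may not be independent. Of the 27 tested members 4 were among the 48 calls (odds ratio 74.4, Fisher's exact p = 6.01e-07), and 18 members were above 0. The family was picked because these 4 were called, so the p value describes the list and does not test it.

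The seed storage genes CRA1 and SESA2 were at 196 and 323 FPKM in dek3-2 replicate 1 and at 5.15 and 3.27 in dek3-2 replicate 2. In dd-2 replicate 2 they were at 17.1 and 13.7.

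For 38 of the 48 genes called in dd-2 both single-mutant means lay between Col-0 and dd-2. That is 79.2 percent. In 100 simulations with unchanged single mutants the 48 genes of lowest p gave 54.8 percent on average and at most 81.3 percent, and 1 simulation reached 38 genes. The simulations called a median of 624 genes, far more than the data, so they are only a rough guide. Log2 changes of dek3-2 against Col-0 and of dd-2 against dek4-2, which share no library, correlated with r = 0.220 across genes, and 0 of 100 simulations gave as large a value. For dek4-2 against Col-0 and dd-2 against dek3-2 r was 0.123, and 3 of 100 simulations gave as large a value. These simulations drew every gene independently. In the data, differences between replicates, which hold no genotype effect, correlated between genotypes at up to 0.230 (Col-0 with dek4-2). Neither count of simulations can therefore show a shared effect of the mutations. Genes are not independent replicates.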
